A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

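Messenger RNA was sequenced from SK1 yeast, a Saccharomyces cerevisiae background that sporulates efficiently, after 4 h in sporulation medium at 30 °C. Per the labels, 2 strains were compared, ndt80 (NDT80 deleted) and ndt80pch2 (NDT80 and PCH2 deleted), with 2 samples each. The labels do not say that the 2 samples of a strain came from separate cultures. The p-values of single genes therefore measure only the spread between these samples, which may be technical.

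Per the submitters' processing notes, FastQC, HISAT2 2.1.0, HTSeq 0.9.1 and DESeq2 2.11.40.6 were among the tools used, with the R64 (sacCer3) build; no role or order is given for them. The authors deposited 1 value per gene and strain, on a TPM-like scale (reads per kb of coding length, scaled to equal totals). No deposited value is given per sample. The deposited TPM-like column has no name in its header, and its unit was inferred from the values. How the column was made is not given in the sources used here. Of the 6682 gene IDs, 6006 were found in the R64 reference annotation used here and 5981 of them had the same coordinates; coordinates below are 1-based, as the deposited tables give them.

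The deposited values were examined as sums of whole reads. Multiplied by coding length, each ndt80pch2 value fell on a sum of whole multiples of 2 fixed steps, 1 per library, for 99.98% of values above 0, within 0.55 of the last printed digit. The same held for all 90 values above 0 in the first 93 rows of the ndt80 column. From row 94, the first mitochondrial row, 9.35% of ndt80 values had such a solution in the printed row order, against 9.48% with the coding length of a random gene as the second term. When the second term was taken from the gene standing in that row of a list without the 18 mitochondrial genes, 99.94% had one. On this reading, the ndt80 column averaged 2 lists by row position, so that 6571 nuclear rows mix 2 genes. Reads per library were computed by solving each value, and were assigned back to their own genes. For 11 genes the annotated coding length gave no solution, and 10 of them were given the 1 length that did. On simulated columns of 6664 genes, 100.0% of the values were recovered exactly. These columns were made with the same steps, coding lengths and row order used to solve them. They therefore test the solving alone and cannot test the reading by row position. Genes unsolved in the data were simulated around a set read number, so the simulation does not cover their difficulty. Of 6664 nuclear genes, 6633 had a value in all 4 libraries, and 31, many of them abundant, were left out. The libraries of a strain are called A and B (ndt80) and C and D (ndt80pch2), since the values do not show which one is replicate 1 or 2.

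Recovered reads over nuclear genes numbered 2103459 in library A, 2365602 in B, 1708432 in C and 1709870 in D. With 3 reads as the floor for a count of 0, which covers counting error only, the floor for PCH2 was 1.26 TPM in library C and 1.29 TPM in D.

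The plan written before the data were examined foresaw limma-trend for normalized values per sample, and a ratio without a test for 1 pooled value per group. For gene lists with pooled values it foresaw a comparison with random lists matched for expression, which is not reported here. The deposited columns are pooled. Recovering libraries from them, and then using the per-sample test, was decided after the data were examined, and several settings were fitted during exploration; all of them are given in the closing section. Genes with a mean recovered TPM of at least 1 (5771) were tested on log2(TPM + 1) with limma 3.58.1 in R 4.3.3 (limma-trend, genotype as the only term) and Benjamini-Hochberg adjustment, with calls at an adjusted p under 0.05. A fold change on this scale understates the change of low genes. The median log2 fold change was -0.15, so fold changes are given relative to the median of all genes, while p-values belong to the change before that subtraction. Gene lists were tested with limma's camera at an inter-gene correlation of 0.01, for lists with at least 3 tested members. At this fixed correlation, camera p-values rest on the spread among genes and not on that between libraries. With 2 libraries per strain they can be too small. Camera with an estimated correlation and fry were run beside the test at the fixed correlation. The estimated correlation rests on 2 residual degrees of freedom, so that test had little power over 27 lists. fry tests a list against no change rather than against the other genes, so the shift of -0.15 works against lists called higher. Lists were fixed before the data were examined, except ergosterol biosynthesis, fatty acid synthesis and desaturation, and ribonucleotide reductase and DNA damage response, which were added after gene values had been seen. Reconstruction and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

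Named genes were PCH2 and NDT80, their 2 neighbours on each side, up to 10 called genes per direction by fold change whose libraries did not overlap (or, with none, the 5 of smallest unadjusted p), up to 4 called members of each list or its 2 most abundant members, of which the text gives examples picked after the values were seen, and marker genes used in strain construction. Other genes named were chosen after their values were seen. The ndt80pch2 against ndt80 comparison was simulated on 5736 genes, 200 of them changed, with the gene-wise spread of the real fit. limma called 20% of 1.5-fold changes, 42% of 2-fold, 78% of 4-fold and 86% of 8-fold changes, and 2 unchanged genes. The simulation gave 115 calls, against 1 in the data. More calls make the adjusted threshold easier to pass, so these shares can overstate what was detectable in the data.

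Alternatives were another pseudocount, no filter, higher filters, other scaling, limma-voom on recovered reads, array weights, a minimum fold and each library left out. The planned edgeR and DESeq2 fits were not run; limma-voom was the method fitted to the recovered reads. The amino acid list was also tested without the genes it shares with the marker list. No reads were assigned here to small noncoding RNA, ribosomal RNA or Ty lists.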

Results

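Transcript levels were compared between meiotic cultures lacking the transcription factor Ndt80 and cultures lacking both Ndt80 and Pch2, an AAA+ ATPase that acts on meiotic chromosomes. Loss of Ndt80 holds cells in meiotic prophase. The comparison asks which transcripts differ when Pch2 is also absent. Each strain had 2 libraries, with 1708432 to 2365602 recovered reads over nuclear genes.

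The deleted genes were examined first. PCH2 (YBR186W, chromosome II, 600553 to 602360, R64) had 710 and 776 reads in the ndt80 libraries, or 243 ± 0.156 TPM (SD, n = 2), and 0 reads in both ndt80pch2 libraries. Against a floor of 3 reads per library, PCH2 was at least 188-fold lower in ndt80pch2 (limma adjusted p = 0.0001178). NDT80 (YHR124W, chromosome VIII, 356561 to 358444) had 0 reads in all 4 libraries, which allows up to 1.16 TPM in the library with the highest floor.

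The deposited ndt80 column reads otherwise if taken row by row. It lists NDT80 at 35.0 in the strain that lacks it, and 1753 of the 5771 tested genes were at least 2-fold apart between the deposited columns. In the recovered and realigned means, 134 were, 67 in each direction. Across genes, which are not independent replicates, Pearson's r of log2(TPM + 1) was 0.71 between the deposited columns and 0.98 between the recovered means. Between single recovered libraries, r was 0.9865 for A and B, 0.9772 for C and D, and 0.9778 to 0.9793 across strains. By r, libraries C and D were therefore no more alike than libraries of different strains. The median absolute log2 difference was 0.1267 between libraries A and B, and 0.2004 between C and D. Between the strains it was 0.2017, but there each strain's 2 libraries were averaged, so the values are not like for like. The strain value also includes the shift of all genes, a median log2 fold change of -0.15. The libraries of the strains did not overlap in 51.9% of tested genes, against 33.3% by chance. That share includes the shift too.

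**Figure D1:**
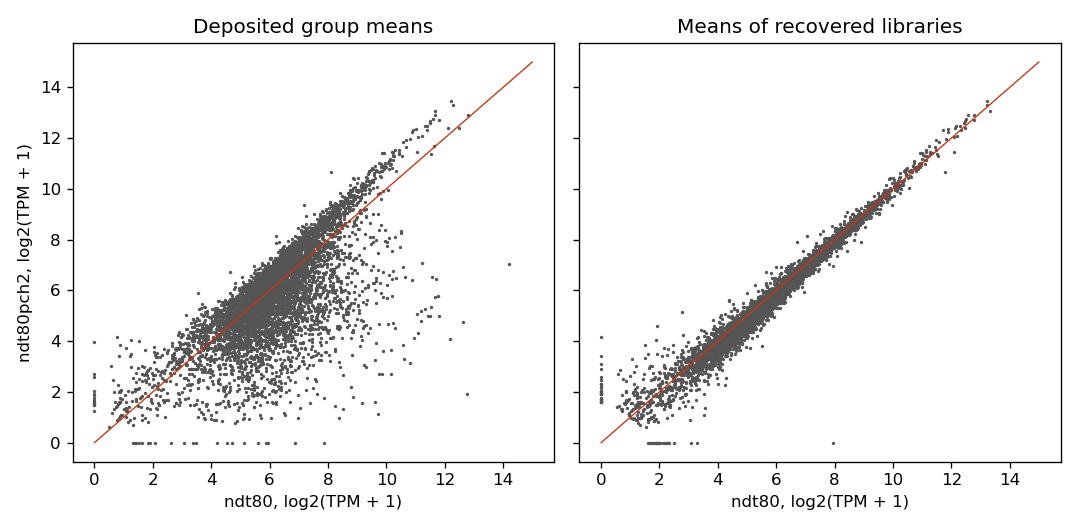
Each point is 1 of 5771 tested genes, with log2(TPM + 1) in ndt80 on the x axis and in ndt80pch2 on the y axis; the line marks equal values. The deposited means (left) scatter with r = 0.71, and the means of the recovered libraries (right) lie close to the line with r = 0.98.

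PCH2 was the 1 gene called by limma-trend; 0 genes were called higher in ndt80pch2. At an unadjusted p under 0.05 there were 915 genes, 155 higher and 760 lower, and 594 after median-of-ratios scaling. limma-voom on the recovered reads called 28 genes, 19 higher and 9 lower. The PCH2 call was lost when either ndt80 library was left out (adjusted p = 0.4938 without A and 0.4979 without B), with the lone library assumed to vary like the other group. The log2 fold change of PCH2 relative to all genes was -7.79 without A and -7.78 without B, against -7.79 with all 4 libraries.

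Values are given for the 5 genes of smallest unadjusted p among those higher in ndt80pch2. None passed limma-trend in the main fit, and all 5 passed by limma-voom on the recovered reads, with adjusted p-values from 0.0005009 (GFD2) to 0.02323 (YAR068W). GFD2 and YAR068W also passed limma-trend with a mean TPM of at least 10 (adjusted p = 0.04905 for both), and RNP1 with no filter (0.02796). With median-of-ratios factors and a mean TPM of at least 10, GFD2 and YAR068W (0.03921) and RNP1, RNR4 and RNR2 (0.04556) passed. GFD2 had 5.89 ± 0.374 TPM in ndt80 and 34.2 ± 0.323 in ndt80pch2 (SD, n = 2; limma adjusted p = 0.07152). YAR068W had 49.6 ± 2.51 and 105.5 ± 0.317 TPM (limma adjusted p = 0.08542). RNP1 had 182.2 ± 1.09 and 294.2 ± 1.57 TPM (limma adjusted p = 0.1362). RNR4 and RNR2, which encode the small subunit of ribonucleotide reductase, had adjusted p-values of 0.1386 and 0.1677 by limma. RNR4 had 345.6 ± 8.69 and 547.5 ± 8.45 TPM, and RNR2 242.7 ± 5.58 and 374.8 ± 15.3 TPM.

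Beside the deletion, MBA1 (YBR185C, chromosome II, 599123 to 599959), which lies next to PCH2 on the other strand, had 37.7 ± 4.18 TPM in ndt80 and 72.5 ± 7.33 in ndt80pch2 (SD, n = 2; limma adjusted p = 0.1978, and 0.04113 by limma-voom). On the other side, GDT1 had 142.5 ± 16.0 and 139.98 ± 11.6 TPM. As a list, the 4 neighbours of PCH2 stood higher relative to all genes, with a median of 0.33 (camera adjusted p = 0.02347; adjusted p = 0.4737 with an estimated correlation), with 1 member, MBA1, passing when adjusted over the list alone. The neighbours did not move together: log2 fold changes relative to all genes were 1.07 for MBA1, 0.53 for NTC20, 0.12 for GDT1 and -0.085 for YBR184W. That list call was lost without library C (median 0.35, adjusted p = 0.07603), without D (0.33, adjusted p = 0.198) and with no filter (0.30, adjusted p = 0.07782). The neighbours of NDT80 were not called (camera adjusted p = 0.2035).

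Marker genes used in strain construction stood apart. Among 8 tested, 4 were higher and 1 lower when adjusted over the list alone, and 0 passed over all genes by limma-trend. Over all genes, limma-voom called TRP1 (adjusted p = 0.007774), ARG4 (0.007774) and LEU2 (0.00854), and limma-trend called TRP1 with median-of-ratios factors and a mean TPM of at least 10 (0.04556). TRP1 had 104.6 ± 9.07 TPM in ndt80 and 240.3 ± 53.4 in ndt80pch2, ARG4 20.01 ± 1.83 and 46.5 ± 3.35, and LEU2 62.8 ± 10.0004 and 119.8 ± 12.8 (SD, n = 2). URA3 had 3 and 5 reads in the ndt80 libraries and 35 and 17 in the ndt80pch2 libraries (adjusted p = 0.05886 by limma-voom). HIS3 had 34.8 ± 0.43 and 16.3 ± 7.43 TPM (adjusted p = 0.1823 by limma-voom). The list had a median of 0.76 relative to all genes and was called higher by camera (adjusted p = 0.0001816; adjusted p = 0.4737 with an estimated correlation). With no filter its median was 0.41 and the call was kept.

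**Figure D2:**
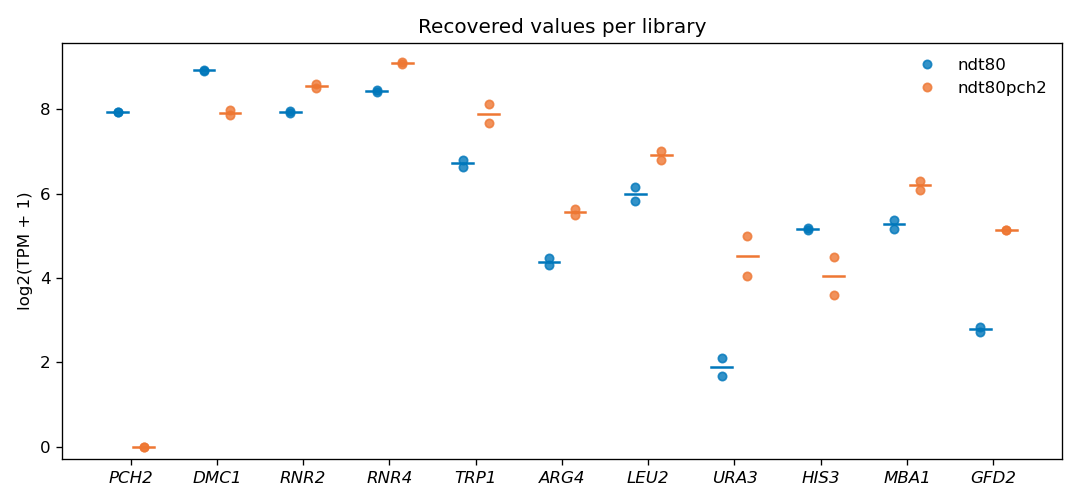
Recovered log2(TPM + 1) of 11 genes in each library, with a bar at the mean of each strain's 2 libraries. PCH2 sits at 0 in both ndt80pch2 libraries, and TRP1, ARG4, LEU2 and URA3 sit higher in ndt80pch2 than in ndt80; DMC1 was chosen after its values were seen.

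The synaptonemal complex and ZMM list, whose proteins join homologous chromosomes and mark crossovers, had a median log2 fold change of 0.26 relative to all genes and was called higher (camera adjusted p = 0.001576; adjusted p = 0.6027 with an estimated correlation). Adjusted over the list alone, 1 member was higher, SPO16, with 204.6 ± 2.81 TPM in ndt80 and 269.3 ± 17.4 in ndt80pch2 (limma adjusted p over all genes = 0.2545, and 0.1271 by limma-voom). Its abundant members SPO22 and GMC2 had 894.8 ± 19.4 and 617.4 ± 4.46 TPM in ndt80, and 998.4 ± 102.0 and 722.9 ± 3.09 in ndt80pch2. Without library D the median of this list was 0.11 and its call was lost (adjusted p = 0.2148). Without A, B or C its medians were 0.17, 0.32 and 0.39, and the call was kept. The other meiotic lists were not called by camera: axis and cohesin (adjusted p = 0.1028), double-strand break formation (0.2932), recombination (0.6014), early regulators (0.3069) and middle sporulation (0.05063). Middle sporulation was called higher with a pseudocount of 0.1 (0.04644), without library B (0.04465), without C (0.01124), and with a mean TPM of at least 5 (0.03042) or 10 (0.02093). Axis and cohesin were called higher without C (0.01203) and with median-of-ratios factors (0.02219). In these lists 0 members passed over all genes by limma-trend in the main fit. Adjusted over the list alone, 1 member of the recombination list (DMC1) and 1 member of the early regulator list (SSP2) were lower. SSP2 also belongs to the middle sporulation list, where 0 members passed when adjusted over that list alone. Its place in the early list therefore does not make it an early regulator. DMC1 had 483.5 ± 10.4 TPM in ndt80 and 241.6 ± 15.3 in ndt80pch2 (limma adjusted p = 0.0704, and 0.0005009 by limma-voom). SPO16, DMC1 and SSP2 were named after their values were seen. SSP2 had 76.2 ± 1.31 TPM in ndt80 and 44.7 ± 8.99 in ndt80pch2 (limma adjusted p = 0.2545, and 0.07825 by limma-voom). REC8, the meiotic cohesin subunit, had 844.7 ± 19.6 and 981.7 ± 97.3 TPM, and IME2, a kinase of meiotic entry, 959.7 ± 95.3 and 1041 ± 127.8 TPM.

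Lists chosen for the link between Pch2, Orc1 and the rDNA were not called: origin recognition and MCM (camera adjusted p = 0.1539), silencing and rDNA maintenance (0.9517), and checkpoint and Dot1 pathway (0.4928). The silencing list had a median of -0.02 relative to all genes although camera placed it upward. Histones were not called either (0.06646), except as lower without library A (0.03269).

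Among metabolic and growth lists, glycolysis and fermentation stood higher relative to all genes, with a median of 0.36 (camera adjusted p = 1.086e-06; adjusted p = 0.6027 with an estimated correlation). Without library C its median was 0.16 and the call was lost (adjusted p = 0.06142), and without B the median was 0.24 and the call was kept. PGK1 had 6158 ± 456.6 TPM in ndt80 and 7764 ± 133.8 in ndt80pch2. Adjusted over the list alone, 1 member passed, and it was lower: HXT1, a glucose transporter gene, had 247.7 ± 3.77 and 121.96 ± 36.7 TPM (limma adjusted p = 0.2545, and 0.007774 by limma-voom). ENO1, a glycolytic enzyme gene, had 3390 ± 355.5 and 5051 ± 248.0 TPM (limma adjusted p = 0.2545), and limma-voom called it higher over all genes (adjusted p = 0.01337).

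The tricarboxylic acid cycle list had a median of 0.18 (camera adjusted p = 0.01762; adjusted p = 0.7363 with an estimated correlation), and the phosphate response 0.09 (0.02208; adjusted p = 0.4737 with an estimated correlation). The first had a median of 0.14 without library A and 0.046 without D and was called in neither fit (adjusted p = 0.3355 and 0.688), and it had 0.30 without C, where the call was kept. The phosphate response was not called without A (median 0.09, adjusted p = 0.1111) or without D (0.06, adjusted p = 0.09131), and had a median of 0.18 without B, where the call was kept. Stress and heat shock genes had a median of 0.14 (0.005458; adjusted p = 0.4737 with an estimated correlation), a call lost without library D (median 0.11, adjusted p = 0.2148) and with no filter (0.11, adjusted p = 0.06756). It was kept without C, where the median was 0.24. The 1 member that passed over the list alone, DDR2, had 6 reads in each ndt80 library and 1 read in each ndt80pch2 library, under the floor of 3 reads, and was not called by limma-voom (adjusted p = 0.332). Amino acid biosynthesis had a median of 0.07 (0.04006; adjusted p = 0.4737 with an estimated correlation), and was not called after median-of-ratios scaling (median 0.07, adjusted p = 0.05149) or with no filter (0.04, adjusted p = 0.06756). It was also not called without library B (median 0.09, adjusted p = 0.0539), C (0.05, adjusted p = 0.2648) or D (0.12, adjusted p = 0.07613). This list shares 5 genes with the marker list, and without them it was not called (adjusted p = 0.1351). Adjusted over the list alone, ARG4 and LEU2, both also markers, were higher, and LEU1 was lower (730.8 ± 9.11 and 520.1 ± 58.3 TPM; adjusted p = 0.05462 by limma-voom). HXT1, ENO1, DDR2 and LEU1 were named after their values were seen.

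Of the lists fixed before the data were examined, ribosome biogenesis was the 1 called lower, with a median of -0.16 (camera adjusted p = 0.002586; adjusted p = 0.7411 with an estimated correlation). Its median was -0.028 without library D and -0.10 without A, and the call was lost in both fits (adjusted p = 0.9101 and 0.1119). It was -0.32 without C, where the call was kept. Cytosolic ribosomal proteins (0.08224), gluconeogenesis (0.2008) and oxidative phosphorylation (0.8461) were not called. Ribosomal proteins were called higher without library A (0.001778), without D (0.002309), with median-of-ratios factors (0.009848) and with a mean TPM of at least 10 (0.043), and gluconeogenesis without B (0.01509).

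Subtelomeric genes, within 20 kb of a chromosome end, had a median of 0.16 relative to all genes (camera adjusted p = 2.02e-07; adjusted p = 0.4737 with an estimated correlation). The list takes every nuclear gene in that range, such as HXK1, also in the glycolysis list, and PHO89, also in the phosphate list. Members of the COS and seripauperin families in that range count in the subtelomeric list too. Adjusted over the list alone, YAR068W and DLD3 were higher and BSC3 was lower, the last 2 named after their values were seen. Over all genes limma-voom called YAR068W (adjusted p = 0.02323) and DLD3 (0.007774), and not BSC3 (0.1271). With median-of-ratios factors and a mean TPM of at least 10, all 3 passed limma-trend (0.03921 for YAR068W, 0.04556 for DLD3 and BSC3). Without library A the list had a median of 0.09 and was called. The COS family had 0.35 (0.0007943; adjusted p = 0.4737 with an estimated correlation) and the seripauperin family 0.06 (0.009537; adjusted p = 0.4737 with an estimated correlation). The COS list had 0.19 without library A and 0.21 with a mean TPM of at least 10, and was called in both. The seripauperin call was lost after median-of-ratios scaling (median 0.04, adjusted p = 0.2331), without library C (0.17, adjusted p = 0.06142), and with a mean TPM of at least 5 (0.16, adjusted p = 0.1781) or 10 (0.04, adjusted p = 0.37). Where the call was kept its median varied too: 0.15 without A, 0.11 without B, 0.39 without D, 0.12 by limma-voom, 0.15 with nuclear genes rescaled, 0.12 with no filter and 0.04 with a pseudocount of 0.1. Some members of both families are closely related copies, and how reads matching several copies were counted is not given in the sources used here, so values of such members are uncertain. The same holds where such members count in the subtelomeric list. Lists for non-sporulating and dividing cells were not called (haploid- and mating-specific, camera adjusted p = 0.7714; vegetative cell cycle, 0.7714).

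Of 27 lists fixed before the data were examined and tested, camera called 12, and 0 were called with an estimated correlation or by fry. With 2 residual degrees of freedom, a list could hardly pass with an estimated correlation, and fry asks a different question. Neither test decides whether the camera calls hold. Camera also set each list against genes of all abundances. The 100 most abundant genes held 29.6% and 30.3% of the recovered values in ndt80, and 32.3% and 33.4% in ndt80pch2. Whether abundance contributed to the list calls was not tested. Without library D, camera called 6.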

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

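The tests on the count of genes in the deposited columns, on recovered nuclear totals and on marker genes were chosen after the result was seen; those on row position, on genotype and on the most abundant genes were set before.

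Reads on the 18 mitochondrially encoded genes were found in data outside the comparison: 67253 reads in ndt80 library A. The lists recovered for libraries B, C and D hold no rows for these genes, so no comparison was made.

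The deposited columns differ at many genes. In the recovered means, the number of genes at least 2-fold apart was 7.64% of that in the deposited columns. Among 90 tested genes in rows before the first mitochondrial row, 0 were 2-fold apart in the deposited columns (a share of 0%), against 30.9% in later rows. Of the genes 2-fold apart in the deposited columns, 4.28% were so in the same direction after realignment, which argues against genotype as the source of most of them. An averaging of 2 lists by row position may account for the pattern, as a hypothesis from the values alone.

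Most genes were slightly lower in ndt80pch2, with a median log2 fold change of -0.15. Rescaling the recovered nuclear genes to equal totals left -0.13, which argues against mitochondrial and unrecovered genes as the whole cause. Leaving out the 100 most abundant genes gave -0.071, between the bounds set for and against them; these genes held 29.6% and 30.3% of the recovered values in ndt80, and 32.3% and 33.4% in ndt80pch2. A larger share in abundant genes may explain part of the shift, and it cannot be told apart from genotype, since the libraries of each strain differ in both.

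Marker genes differed between the strains, 5 of them when adjusted over the list alone. Regulation of their pathways could move the other genes of the uracil, tryptophan, arginine and leucine pathways too, but these 16 genes had a median of -0.025 relative to all genes (quartiles -0.18 and 0.05). The histidine pathway of HIS3 was not among them, and a median pooled over pathways cannot exclude regulation of a single pathway. Different marker alleles from strain construction stay open and cannot be told apart from an effect of PCH2, because the labels used here give no marker genotype.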

How the results depend on the processing

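Settings chosen after the data were examined were other scaling, higher filters, a nonzero filter, array weights, a minimum fold, the amino acid list without marker genes and the deposited means; the cause of changes was not tested unless given. limma-trend called 1 gene, PCH2, also with a pseudocount of 0.1, with a nonzero filter, with median-of-ratios or upper-quartile factors, with nuclear genes rescaled, and against a 1.5-fold change. With no filter it called 25 genes (14 higher, 11 lower), where genes without variance entered the fit. limma-voom called 28 (19 higher, 9 lower), a mean of at least 5 gave 2 (0 higher, 2 lower), a mean of at least 10 gave 4 (2 higher, 2 lower), median-of-ratios factors with a mean of at least 10 gave 10 (7 higher, 3 lower), and array weights gave 2 (0 higher, 2 lower). With 1 library left out, calls ranged from 0 to 1, all lower, and the PCH2 call was lost without either ndt80 library, at a log2 fold change of -7.79 and -7.78. Genes at least 2-fold apart numbered 134, or 1753 in the deposited means, and 197 to 261 with 1 library left out.

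Of the lists fixed before the data were examined, camera called 12, 6 to 13 with 1 library left out, and 0 with an estimated correlation or by fry. With median-of-ratios factors the amino acid (adjusted p = 0.05149) and seripauperin (adjusted p = 0.2331) lists were no longer called, and axis and cohesin (0.02219) and ribosomal proteins (0.009848) were. At the fixed correlation, the marker, COS and subtelomeric lists were the ones called in every setting. COS genes near a chromosome end count in the subtelomeric list too, so the COS and subtelomeric calls need not be independent. For the other lists, calls lost or gained in planned settings stand beside each list above. Without its 5 marker genes the amino acid list was not called (adjusted p = 0.1351), and 11 lists were. Lists whose direction by camera turned were not called in the setting reported above; their medians relative to all genes follow. Silencing had -0.051 with no filter, -0.023 with a nonzero filter and -0.025 by limma-voom. The vegetative list had -0.13 with no filter, -0.13 by limma-voom, -0.12 with median-of-ratios and -0.12 with upper-quartile factors, and 0.053 with median-of-ratios factors and a mean of at least 10. Oxidative phosphorylation had 0.024 by limma-voom, 0.026 with median-of-ratios, 0.025 with upper-quartile factors, 0.024 with a mean of at least 10 and 0.026 with both. With 1 library left out, medians ranged from -0.021 to 0.038 for silencing, 0.051 to 0.20 for early regulators, -0.018 to 0.17 for gluconeogenesis, -0.029 to 0.022 for oxidative phosphorylation, 0.029 to 0.14 for ribosomal proteins and -0.071 to 0.028 for the vegetative list. RNR1 had -0.027 with no filter and -0.060 to 0.059 with 1 library left out.

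No paired analysis was possible because the recovered libraries carry no replicate number. The planned edgeR and DESeq2 fits were left out and not run; limma-voom was the method fitted to the recovered reads. Depth limits low genes such as URA3, with 3 and 5 reads in ndt80.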

Other observations

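Except MEI5, the genes and lists here were chosen after their values were seen, and none of the genes passed limma-trend in the setting reported above.

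DMC1, the meiosis-specific recombinase, had a limma adjusted p of 0.0704, of 0.0005009 by limma-voom and of 0.04769 with a mean TPM of at least 5. limma-trend also called it with a mean TPM of at least 10 (0.04096, and 0.04556 with median-of-ratios factors added) and with array weights (0.03715). DMC1 was not called by limma-trend with a pseudocount of 0.1 (0.09295), with median-of-ratios factors alone (0.0816) or with upper-quartile factors (0.06956). Nor was it called with no filter (0.1463), with a nonzero filter (0.09264) or with nuclear genes rescaled (0.07827). With 1 library left out, its log2 fold change relative to all genes ranged from -0.93 to -0.78. limma-voom also called RNR3 (adjusted p = 0.0178) higher, and ERG11 and OLE1 (0.007774 for both) lower. MEI5, which acts with Dmc1, had 596.1 ± 0.251 and 648.3 ± 58.3 TPM. RNR3, a subunit of ribonucleotide reductase, had 15.9 ± 0.795 and 30.0 ± 1.1 TPM, and RNR1 113.4 ± 1.34 and 102.7 ± 4.8 TPM. The list of ribonucleotide reductase and DNA damage response genes had a median log2 fold change of 0.61 relative to all genes (camera adjusted p = 1.067e-07; adjusted p = 0.1058 with an estimated correlation).

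Of 24 ergosterol biosynthesis genes, 22 had a negative log2 fold change before the median was subtracted. That count includes the shift of all genes, whose median was -0.15. Among lists not called, 13 of 14 origin recognition and MCM genes were negative, 26 of 30 vegetative genes, and 6 of 11 axis and cohesin genes. The ergosterol list had a median of -0.22 relative to all genes (camera adjusted p = 9.082e-06; adjusted p = 0.1058 with an estimated correlation). ERG11 had 224.0 ± 15.4 TPM in ndt80 and 131.8 ± 14.4 in ndt80pch2. Fatty acid synthesis and desaturation genes had a median of -0.08 (camera adjusted p = 0.0371; adjusted p = 0.3923 with an estimated correlation). OLE1, the fatty acid desaturase, had 4405 ± 238.2 and 2831 ± 33.9 TPM. By fry, adjusted over these added lists alone, ribonucleotide reductase (adjusted p = 0.02756) and ergosterol (0.01289) passed and fatty acid synthesis (0.08236) did not. fry tests against no change, so these p-values belong to the changes before the median was subtracted. The list medians were then 0.46, -0.37 and -0.23, in the same order. Left-out libraries, other filters and other scaling were not tried for the lists given here. These lists were built from genes already seen to differ, so their tests are not independent evidence.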
